A study of Bos taurus with 4 samples.

How the data were processed

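Granulosa cells, the somatic cells that surround and support the oocyte in the ovarian follicle, were profiled on 4 two-colour arrays of cattle probes. Per the labels, the cells came from Holstein animals after ovarian stimulation and coasting (a pause without hormone before collection), were combined into pools by the developmental competence of the donors' oocytes, and total RNA of each pool was amplified linearly before dye labelling. The design text speaks of 94 heifers and cows and sets competent oocytes of cows against incompetent oocytes of heifers, while the title and all array labels speak of heifers. Whether the good-donor pools came from cows or from heifers is therefore not settled by the labels used here, and neither is the number of animals in a pool or whether an animal entered more than 1 pool. The p-values measure the spread of the good over poor ratios between the arrays. That spread holds differences between these pools together with any dye effect and measurement noise, and it does not measure the spread between animals.

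Each array held 1 good-donor and 1 poor-donor pool, so the 4 arrays hold 4 good-donor and 4 poor-donor pools. Arrays 1 and 2 had the good-donor pool in Cy5 and the poor-donor pool in Cy3, and arrays 3 and 4 had the dyes exchanged. The 4 arrays were on 1 slide, so no slide effect can enter the comparison. Per the file headers, the deposited scanner files hold mean and median foreground and background intensity per spot at 635 nm (Cy5) and 532 nm (Cy3) on a linear scale, with no spot flags and no background standard deviation. The scanner and its software are not given in the sources used here. The authors also deposited a table of normalized log2 ratios whose method and direction are not given. Set against the scanner ratios, its values had Pearson's r of -0.98, -0.97, 0.96 and 0.98 with Cy5 over Cy3 on arrays 1 to 4 and slopes near 1 in size, so all 4 columns are log2 of poor over good. The medians of these columns were 0.023, 0.0039, -0.015 and -0.029. The method of its normalization stays unknown, and it was used as an alternative only.

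Mean foreground intensity was corrected with median local background by normexp with an offset of 50, ratios were normalized by loess within each array with control spots at weight 0, and average levels by Aquantile between arrays (limma 3.58.1 in R 4.3.3). Every probe had 1 spot. Of 43794 probes, 31917 entered the tests because their foreground exceeded the 95th percentile of the dark and negative control spots of that channel in at least 4 of 8 channels. This is the last of the filters fixed before the data were examined, used because the files hold neither flags nor background spread. Each ratio was turned to good over poor by the dye labels. limma's lmFit and eBayes tested the mean of the 4 ratios against 0, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 3 residual and 1.97 prior degrees of freedom. Gene names come from the platform annotation, which is old. It gave 1 symbol to 21790 probes, several to 0 and none to 22004. Of 15229 symbols, 14114 were in the RefSeq gene table of assembly ARS-UCD2.0, 982 were updated through a synonym listed for a single gene, and 133 were kept. The tested probes with a symbol covered 12598 genes, each represented by its brightest probe. No coordinates are given.

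The comparisons, the alternatives, the named genes and 25 gene lists were fixed before the data were examined. The lists cover granulosa functions, metabolism, signalling and markers of other cell types that a follicular aspirate could hold. They were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, over lists with 5 or more measured genes. The rule for named genes took genes past the adjusted threshold. With fewer than 10 such genes it took up to 12 genes in each direction with the smallest unadjusted p among those with the same sign on all 4 arrays and a mean change of at least 1.5-fold. It added up to 4 members with the smallest p from each list that passed and from the steroidogenesis, growing follicle and LH surge lists, and 8 granulosa identity genes. Only 9 genes met the rule in the higher direction and 64 in the lower. At most 2 unnamed probes were named by their ID in each direction.

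Alternatives changed the background correction, the normalization, the filter, the dye term, the model (separate channels, with statmod 1.5.0), the spread, the array weights, the source of values, the threshold and the arrays included. On simulated data with the spread of each real probe, the good over poor test over 31917 probes recovered 63.0% of 100 probes changed by 1 on the log2 scale and 90.0% of 100 probes changed by 2, and 8 of 31717 unchanged probes passed, while 137 of them met the looser rule of an unadjusted p under 0.05 and a mean change of at least 1.5-fold. The simulated ratios were drawn independently for each array from a normal distribution, so relations between the arrays were left out. Figures were drawn with matplotlib 3.10.9.

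Signal over background limits the precision of dim probes, and the number of arrays limits the precision of every ratio. The share of probes above background ranged from 66.3% to 74.7% per channel, and the median probe lay between 1.11 and 1.20 times the background threshold.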

Results

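Gene expression was compared between granulosa cells of cattle rated as good and as poor donors of developmentally competent oocytes. The question was which transcripts differ between the follicles of these donors. On each of 4 arrays, 1 good-donor pool was hybridised directly against 1 poor-donor pool, which gave 4 good-donor and 4 poor-donor pools in all. The good-donor pool was in Cy5 on 2 arrays and in Cy3 on the other 2. Median foreground intensity ranged from 49.9 to 54.3 in the Cy5 channels and from 90.5 to 132 in the Cy3 channels. Values below are log2 ratios of good over poor with the SD over 4 arrays, so a negative value means a lower signal in good-donor pools; the deposited ratios run the other way, as poor over good. The labels used here leave open whether the good donors were cows or heifers, so a difference in age class between the groups is not excluded.

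The pools held abundant granulosa transcripts. INHA and INHBA, which encode inhibin and activin subunits, had mean log2 intensities of 15.16 ± 0.39 and 15.05 ± 0.66 (SD, n = 4) in good-donor pools and 14.67 ± 0.81 and 14.88 ± 0.87 (SD, n = 4) in poor-donor pools. CYP19A1, the aromatase that makes oestrogens, reached 12.74 ± 0.47 in good-donor and 12.64 ± 0.52 in poor-donor pools (SD, n = 4). CYP11A1, which catalyses the first step of steroid synthesis from cholesterol, reached 12.91 ± 0.49 and 12.54 ± 0.81 (SD, n = 4). The follicle-stimulating hormone receptor FSHR lay at 10.14 ± 0.15 and 9.93 ± 0.13, and AMH, the anti-Müllerian hormone, at 9.56 ± 0.36 and 9.41 ± 0.41 (SD, n = 4). The LH receptor LHCGR (6.997 ± 0.28 and 6.72 ± 0.23) and the transcription factor FOXL2 (6.48 ± 0.12 and 6.31 ± 0.06) were dim, and FOXL2 was above background in all 4 good-donor pools and in 2 of 4 poor-donor pools.

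**Figure D1:**
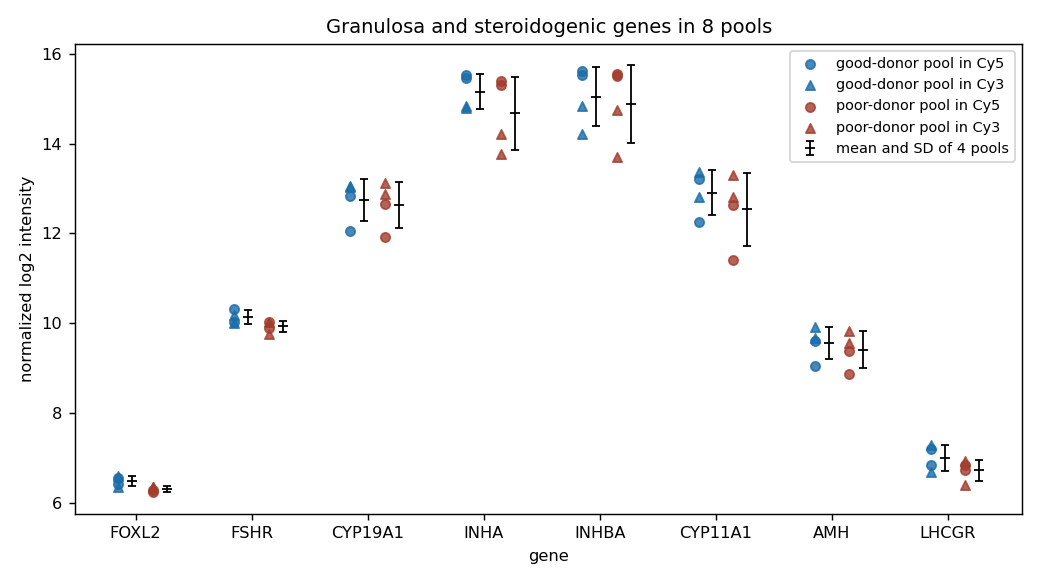
Normalized log2 intensity (vertical axis) of 8 granulosa and steroidogenic genes in each of the 8 pools, with circles for pools in Cy5, triangles for pools in Cy3 and bars for the mean and SD of 4 pools. Good-donor and poor-donor pools overlap for all 8 genes, and for INHA and INHBA the pools in Cy5 lie above those in Cy3.

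None of these 8 genes passed the adjusted threshold between the donor groups (limma adjusted p = 1 for each). The mean log2 ratio was 0.48 ± 1.20 for INHA, 0.17 ± 1.47 for INHBA, 0.11 ± 0.84 for CYP19A1, 0.37 ± 1.10 for CYP11A1, 0.15 ± 0.70 for AMH, 0.21 ± 0.25 for FSHR, 0.28 ± 0.22 for LHCGR and 0.17 ± 0.11 for FOXL2 (SD, n = 4). FOXL2 and FSHR were higher in the good-donor pool on 4 of 4 arrays and LHCGR on 3 of 4, with unadjusted limma p-values of 0.044, 0.108 and 0.037. The SD over arrays exceeded the mean for FSHR and for INHA, INHBA, CYP19A1, CYP11A1 and AMH. INHA and INHBA were higher in the good-donor pool on both arrays with that pool in Cy5 and lower on both arrays with it in Cy3, so their ratios followed the dye. The INHBA probe was at 99.5% or more of the brightest probe of the Cy5 channel on every array, and the INHA probe at 89.1% or more. INHBA was itself that brightest probe on arrays 1 and 3. In Cy3 it lay between 41.8% and 96.8% of the brightest probe, and INHA between 43.8% and 100%. Whether signals near the top of the scale compress these ratios was not tested, so the size of each is uncertain. Without array 4, the mean turned to -0.16 for CYP11A1, -0.23 for CYP19A1 and -0.07 for AMH.

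No probe passed the adjusted threshold between good-donor and poor-donor pools. Of 31917 probes tested with limma, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.614. An unadjusted p under 0.05 was found for 1133 probes, of which 696 were higher and 437 lower in good-donor pools, against 1596 by chance. This chance count takes the arrays as independent and free of dye effects, so it is no exact level for these data. The same test with separate channels, a dye term, an intensity trend or array weights also gave 0 probes, with 1113, 1838, 864 and 1212 probes at an unadjusted p under 0.05. A looser count, not controlled for multiple tests, held 73 probes with an unadjusted p under 0.05 and at least a 1.5-fold mean change, 29 higher and 44 lower. On simulated data with the spread of the real probes, 137 of 31717 unchanged probes met this looser rule. The simulation left out relations between the arrays, so this is no exact chance level. Of the 73 real probes, 61 had the same sign on all 4 arrays. This looser count was 351 without array 1, 140 without array 2 and 118 without array 3.

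Among named genes with the same sign on 4 arrays and at least a 1.5-fold change, 9 were higher and 64 lower in good-donor pools. The 21 genes named by the fixed rule did not pass the adjusted threshold. APOA1, the main apolipoprotein of high-density lipoprotein, had the smallest p, with a mean log2 ratio of 0.88 ± 0.08 (SD, n = 4), 1.84-fold higher in good-donor pools (probe EMBV3_07752, limma adjusted p = 0.614). Its ratio lay between 0.79 and 0.97 on the 4 arrays, and a second probe gave 0.72. The other 8 genes on the higher side had mean ratios from 0.59 to 0.69. They included NR3C1, the glucocorticoid receptor, at 0.60 ± 0.36, AKT2, a kinase of insulin signalling, at 0.59 ± 0.34, KIF3A, a kinesin motor subunit, at 0.62 ± 0.17, and CREB3L2, a transcription factor held in the endoplasmic reticulum, at 0.69 ± 0.27 (SD, n = 4). SLC30A7, a zinc transporter, had 0.65 ± 0.26, and ZBTB21, LOC512672 and RUNX1T1 had 0.61 ± 0.40, 0.62 ± 0.42 and 0.62 ± 0.54 (SD, n = 4). LOC512672 was above background in 3 of 4 poor-donor pools, so the size of its ratio is uncertain. The other ZBTB21 probe gave 0.14, and the other KIF3A probes gave -0.04 and 0.17.

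The genes on the lower side had larger and more variable ratios. TAP and LAP, which encode tracheal and lingual antimicrobial peptides of the beta-defensin family, had mean log2 ratios of -2.99 ± 1.99 and -2.66 ± 1.85 (SD, n = 4). These correspond to 7.96-fold and 6.33-fold higher signals in poor-donor pools. Close relatives within this family can share probe signal, so these values are uncertain as to the gene. PIGR, the receptor that carries polymeric immunoglobulins across epithelia, had -1.82 ± 1.23, WFDC2 -1.50 ± 1.05 and CLCA1 -1.15 ± 0.78 (SD, n = 4). The other PIGR probes gave -1.70 and -0.26. IL1A, a cytokine, had -1.17 ± 0.59 and VAV3 -1.07 ± 0.69 (SD, n = 4). LOC784768 had -2.92 ± 1.60 and was above background in 2 of 4 good-donor and in 4 poor-donor pools, so the size of this ratio is uncertain. USP50 was the least variable of this side at -0.82 ± 0.16, and PUSL1, PARM1 and GLUL, the last of which encodes glutamine synthetase, had -0.90 ± 0.53, -0.89 ± 0.61 and -0.67 ± 0.42 (SD, n = 4). The other 3 PUSL1 probes gave -0.06, -0.02 and 0.0021, so its change was in 1 of 4 probes. Array 4 held the most negative ratio for all of these except PUSL1. limma's adjusted p was 1 for each gene on this side.

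**Figure D2:**
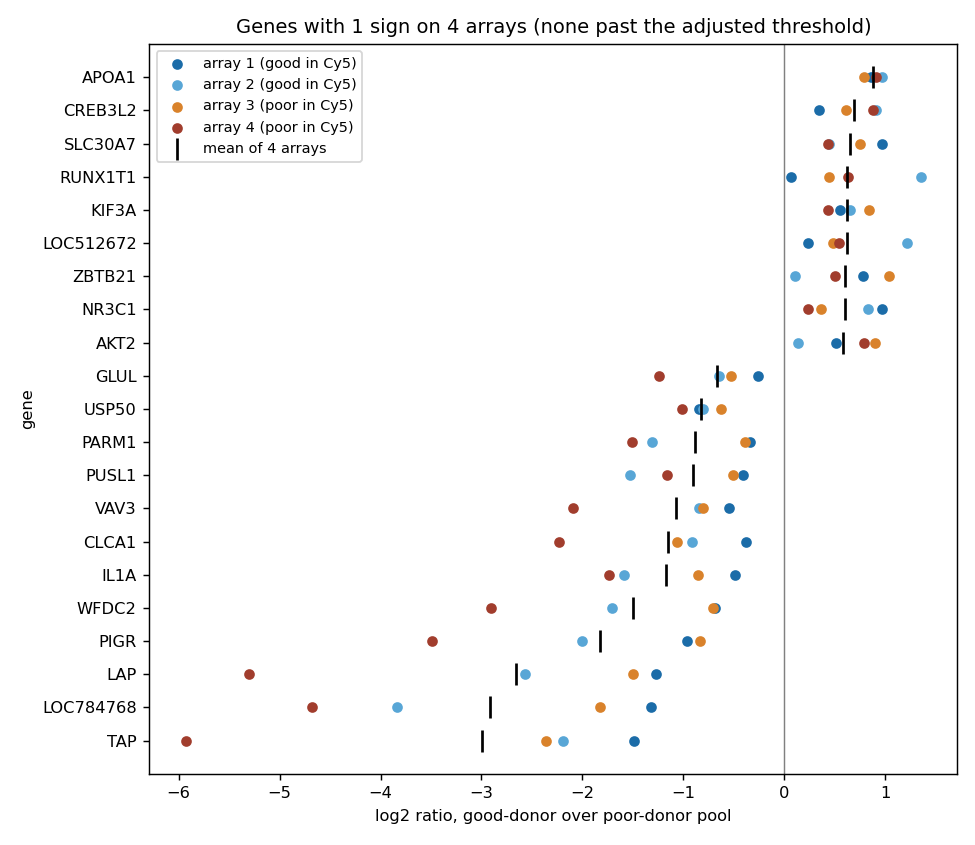
Log2 ratio of good-donor over poor-donor pool (horizontal axis) for the 21 genes named by rank, with a point for each of 4 arrays and a bar for their mean. APOA1 lies between 0.79 and 0.97 on the 4 arrays, while TAP ranges from -1.49 on array 1 to -5.93 on array 4.

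Of the 73 probes of the looser count, 26 had no gene name, 11 higher and 15 lower. EMBV3_42009 and EMBV3_12200 had mean log2 ratios of 0.74 ± 0.17 and 0.78 ± 0.21, and EMBV3_20528 and EMBV3_24507 had -1.58 ± 0.86 and -3.12 ± 2.11 (SD, n = 4), with a limma adjusted p of 1 for each.

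Of 25 gene lists, 3 passed camera at the preset correlation, all lower in good-donor pools. None of the 25 passed with an estimated correlation (smallest adjusted p = 0.754 with an estimated correlation) or with fry (smallest adjusted p = 0.860). The estimate was 0.80 for leukocyte markers, 0.49 for epithelium markers and 0.24 for inflammatory cytokines, against the preset 0.01. Members of these lists are therefore far from independent, and counts of members overstate the evidence. Leukocyte markers fell, with 24 of 25 measured members lower, a median log2 ratio of -0.21 and an adjusted p of 8.4e-05. S100A9 and S100A8, calcium-binding proteins abundant in neutrophils, had -1.84 ± 1.97 and -1.42 ± 1.63, CD14, a monocyte receptor, -0.72 ± 0.74, and CD3D, a chain of the T-cell receptor complex, -0.62 ± 0.61 (SD, n = 4). The list's median was 0.12, -0.25, 0.03 and -1.13 on arrays 1 to 4. Markers of surface and oviduct epithelium fell, with 13 of 16 members lower, a median of -0.50 and an adjusted p of 0.0036. EPCAM and CLDN4, proteins of epithelial cell contacts, had -1.37 ± 1.15 and -1.34 ± 1.68, KRT7, a keratin, -0.93 ± 1.28, and CLDN7 -0.32 ± 0.38 (SD, n = 4). The other EPCAM probe gave 0.02. This list's median was 0.41, -0.66, -0.56 and -1.05 on arrays 1 to 4. Inflammatory cytokine genes fell, with 18 of 22 members lower, a median of -0.08 and an adjusted p of 0.012. Beside IL1A, given above, CXCL5 had -1.47 ± 1.51, TNF -0.15 ± 0.12 and IL6 -0.10 ± 0.04 (SD, n = 4), and the other IL6 probe gave 0.01. In good-donor pools the CXCL5 probe was above background in 3 of 4 and the IL6 probe named first in 2 of 4, so the sizes of these ratios are uncertain.

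No member of these 3 lists passed over all genes tested, and 0 passed when adjusted over the list alone. Without array 4 the adjusted p was 0.507 for leukocyte markers, 0.269 for epithelium markers and 0.458 for inflammatory cytokines, and the medians were -0.03, -0.17 and -0.02. For inflammatory cytokines it was 0.121 without array 2 and 0.115 over probes above background in all 8 channels. The medians of all 3 lists were below 0 on arrays 2 and 4 and above 0 on array 1.

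**Figure D3:**
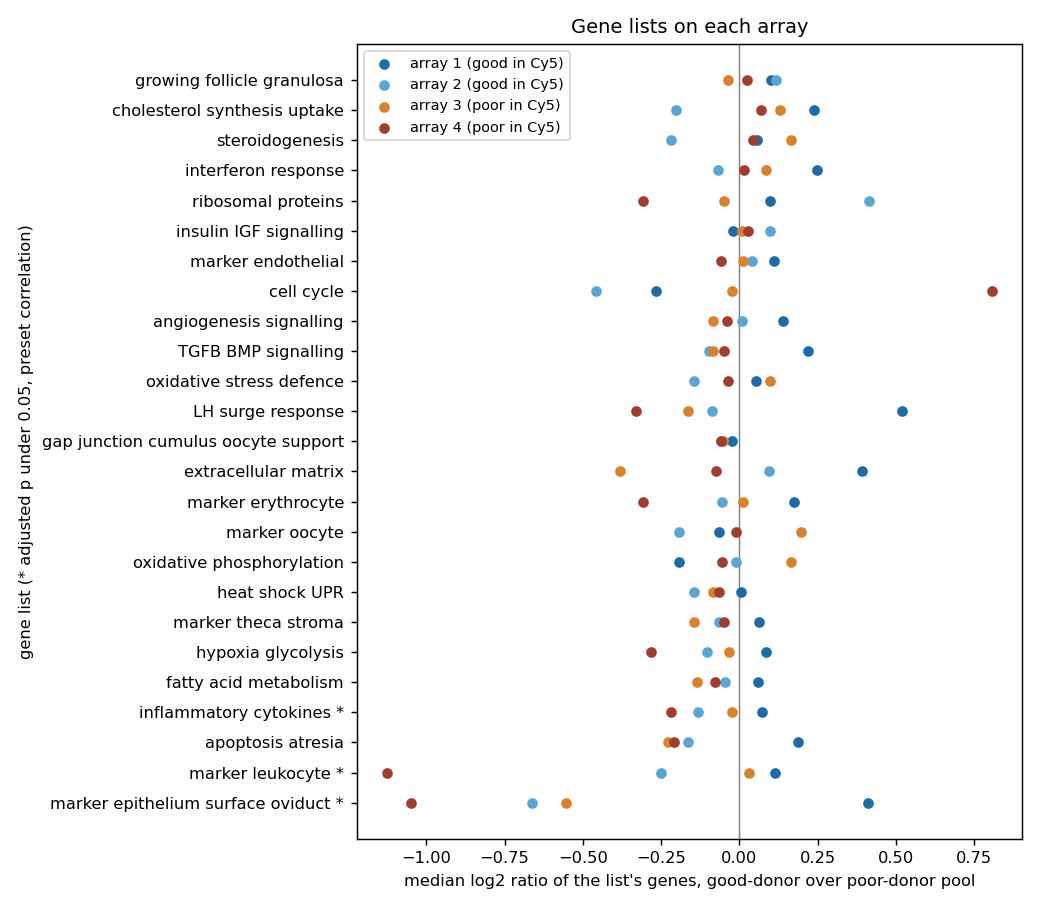
Median log2 ratio of good-donor over poor-donor pool (horizontal axis) of the measured genes of 25 gene lists, with a point for each of 4 arrays and a star at lists past the adjusted threshold with the preset correlation. Leukocyte markers lie at -1.13 on array 4 and at 0.12 on array 1, and cell cycle genes lie at 0.81 on array 4 and at or below -0.02 on the others.

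The lists for steroid synthesis, the growing follicle and the response to the LH surge did not pass. Steroidogenesis genes had 10 of 15 members higher and a median of 0.08 (limma camera adjusted p = 0.251). POR, the electron donor of microsomal cytochromes P450, had 0.30 ± 0.23, HSD17B1, which converts oestrone to oestradiol, 0.50 ± 0.54, HSD17B4 0.11 ± 0.04, and the nuclear receptor NR5A2 0.14 ± 0.24 (SD, n = 4). The other NR5A2 probes gave -0.10 and 0.37. Growing follicle genes had 15 of 22 members higher and a median of 0.12 (adjusted p = 0.149). GATA4, a transcription factor of granulosa cells, had 0.30 ± 0.28 and MRO 0.40 ± 0.68 (SD, n = 4). LH surge genes had 11 of 24 members higher, and their median of -0.01 and mean of -0.15 lay opposite to the direction of their test (adjusted p = 0.838). NRIP1, a nuclear receptor corepressor, had 0.40 ± 0.45 (0.02 with its other probe), the progesterone receptor PGR 0.23 ± 0.29 and VNN2, a pantetheinase, -1.49 ± 2.11 (SD, n = 4). In these 3 lists 0 members passed, over all genes or adjusted over the list alone. The calls depended on single arrays, since steroidogenesis passed without array 2 (adjusted p = 0.0315), growing follicle genes without array 3 (adjusted p = 0.0252) and LH surge genes without array 1 (adjusted p = 0.0213). Growing follicle genes also passed with a dye term (adjusted p = 0.0315) and with median centring (adjusted p = 0.0375).

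The 4 arrays did not share a common good over poor pattern. Across the 31917 tested probes, which are not independent replicates, Pearson's r of the log2 ratios was -0.34 between arrays 1 and 3, 0.29 between arrays 3 and 4, and between -0.07 and 0.06 for the other 4 pairs. The same sign on all 4 arrays was found for 2960 probes (9.27%), against 12.5% by chance for independent arrays. The correlations above show that these arrays were not independent. A dye effect would also lower this share, so the difference from 12.5% decides nothing about the donors. Array 4 had the widest ratios, with an SD of 0.419 and 876 probes at 2-fold or more, against SDs of 0.274 to 0.317 on the other arrays.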

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

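All tests of the opposed arrays, and for the epithelial genes the test of a dye effect and that of array 4 over arrays 2 and 3, were chosen only after the result was seen; the comparisons with random lists over all arrays and without array 4 were chosen before. Of 91 sets of 4 values examined for a sample far from the others, 4 stood out, against 4.55 by chance. In each, array 1 lay apart. The log2 ratio of HSD17B1 was -0.31 on array 1 and 0.72 to 0.84 on the others, and that of PGR was -0.20 against 0.31 to 0.40. The median of apoptosis and atresia genes was 0.19 on array 1 and -0.23 to -0.16 on the others, and that of TGF-beta and BMP signalling genes was 0.22 against -0.10 to -0.05.

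Of 74 genes and lists, 8 had a good over poor ratio of a given sign on both arrays with the good-donor pool in Cy5 and the opposite sign on both other arrays. By chance 12.5% of such sets reach this if the arrays are independent. With the good-donor pool in Cy5 and then in Cy3, the means were 1.51 and -0.54 for INHA, 1.35 and -1.01 for INHBA, and 0.97 and -0.18 for MRO. They were -0.55 and 0.77 for CYP19A1, and -0.33 and 1.07 for CYP11A1. INHA and INHBA lay near the brightest Cy5 signal, so the sizes of their ratios are uncertain. The dye term of the limma fit had adjusted p-values of 0.179, 0.227, 0.199, 0.247 and 0.394 for INHA, INHBA, MRO, CYP19A1 and CYP11A1. The list medians were 0.073 and -0.062 for angiogenesis, 0.24 and -0.23 for extracellular matrix, and 0.26 and -0.18 for ribosomal proteins, and these list differences were not tested. Over all probes the dye term passed for 0, with 5301 at an unadjusted limma p under 0.05, against 1596 by chance. The 0 passing therefore does not mean that dye effects are absent.

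Some probes of epithelial genes had lower signals in good-donor pools on all 4 arrays, with none past the adjusted threshold. KRT4, a keratin of mucosal epithelia singled out after its values were seen, had log2 ratios of -1.07, -3.34, -2.13 and -6.33 on arrays 1 to 4, beside PIGR, EPCAM, TAP and LAP (limma adjusted p = 1 for each), while the other EPCAM probe gave 0.02. A candidate explanation is RNA of epithelial cells of another tissue in the poor-donor pools. It was tested on 42 squamous and mucosal epithelium genes listed without the genes that showed the pattern, of which 0 are in the fixed lists and 32 were above background in all 4 good-donor pools. Their median of -0.09 had a percentile of 0 among 10000 random lists matched on level. These lists were not matched on the correlation between genes, which was estimated at 0.49 for the fixed list of epithelium markers. A shift of correlated genes in a single pool can therefore reach such a percentile, and no percentile given here allows for it. The 19 squamous genes had -0.17, also at a percentile of 0 (0.02 at the 70.3 percentile without array 4), and the 23 mucosal genes -0.04 at the 4.29 percentile, inside the central 95%. A lower mean was found for 29 of the 42, a lower signal on all 4 arrays for 0, and on arrays 2 to 4 for 10, against 5.25 by chance for independent arrays and genes. Arrays 3 and 4 had r = 0.29 over the tested probes, and the count leaves out array 1, so it decides nothing. A dye effect of one size on all arrays was argued against as the whole cause, within the limit of these random lists. Such an effect cancels in a mean with each dye orientation on 2 arrays. The median of -0.094 of the 42 genes lay below -0.03, the 2.5th percentile of the random lists. Without array 4 it was 0.01 at the 66.1 percentile, so the verdict on a dye effect rests on array 4. Arrays 3 and 4, with the same orientation, had medians of -0.03 and -0.42. The first form of this test, replaced after its result was seen, compared the medians with the good-donor pool in Cy5 (0.043) and in Cy3 (-0.26) and decided nothing. The pools of array 4 alone cannot be told apart as a source. The first form of this test came out in favour of array 4 alone, with a median of 0.01 at the 66.1 percentile without array 4. It was replaced after its result was seen, and the rule that leaves the source undecided was set after the value of array 2 was seen. Over arrays 2 and 3 the median was -0.02 at the 14.85 percentile, but on array 2 it was -0.11 at the 0.11 percentile. The squamous genes had medians of 0.04, 0.03, -0.05 and -0.76 on arrays 1 to 4, so their shift rests on array 4, and the mucosal genes had -0.16 on array 2. On array 1 the median of all 42 was 0.10, at the 98.7 percentile. There the fixed list of surface and oviduct epithelium markers had a median of 0.41, so most of its signal was higher in the good-donor pool of that array. KRT4, PIGR, TAP and LAP went the other way on array 1, at -1.07, -0.96, -1.49 and -1.28. Epithelial genes therefore did not share a direction on that array. The brightest members, LTF and TFF3, had 1.49, -1.48, -2.28 and -3.94, and 0.69, -1.63, -2.28 and -3.40, on arrays 1 to 4. A difference between donors stays open and untested.

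The good over poor ratios of arrays 1 and 3 ran against each other (r = -0.34), with opposed signs for 391 of the 476 probes at 1.5-fold or more on both. A gene-specific dye effect as the whole cause was argued against, since 32.7% of these 391 probes kept their Cy5 over Cy3 sign on array 2 and 68.0% on array 4 (a first form of this test, replaced after its result was seen, found correlations above 0 in 2 of the 4 pairs of arrays with opposite dyes). Exchanged wavelengths were argued against too, since ratios of 28 spiked controls correlated at 0.989 or more between all pairs of arrays. Exchanged good-donor and poor-donor pools on array 1 stay open: of 500 probes with a common sign and a mean change of at least 1.5-fold on arrays 2 to 4, 28.4% had that sign on array 1. The share was 114 of 442 for lower probes but 28 of 58 for higher ones, which an exchange would also reverse, and 22 of 50 for the largest changes, so this decides nothing (a first form of the test, on the share over all of these probes, came out in favour of an exchange; the demand on higher and lower probes was added after their values were seen). With array 1 turned, the looser count was 324 probes, against 73. Pools that differ in their donors or cell content could give the same values, and neither this nor an exchange on array 3 was tested.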

How the results depend on the processing

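All alternatives here were fixed before the data were examined, and all of them gave 0 probes past the adjusted threshold, with smallest adjusted p-values from 0.064 (separate channels) to 1. With 8 ways to turn the ratios of the 4 arrays, the splits are too few for a share under 0.05. As many probes as the real 0 came from 8 of 8, the highest other being 0. As many as the real 73 came from 6 of 8, the highest other being 324 (11 lists), with array 1 turned against the others. As many as the real 3 lists came from 8 of 8, the highest other being 12. The split by dye alone gave 221 probes by the looser count (the donor comparison gave 90 with a dye term in the fit) and 5783 at an unadjusted p under 0.05, against 1133 in the donor comparison and 1596 by chance, which points to a structure of the arrays by dye. For the looser counts, 137 unchanged probes met the rule on simulated data, more than the real 73. The simulation drew each array independently, while the real ratios of arrays 1 and 3 ran against each other (r = -0.34). The 137 is therefore no exact chance level for the real count.

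The looser count of 73 probes was 161 with the deposited series values, 143 with plain background subtraction, 116 with an intensity trend, and 71 to 351 when an array was left out (118 to 351 where it moved by over 1.5-fold). The 3 lists became 0 with an estimated inter-gene correlation, 0 with fry, 6 with median centring, 2 over probes above background in all 8 channels (inflammatory cytokines fell away, adjusted p = 0.115), and 1 to 7 when an array was left out. Without array 4 the list that passed was cell cycle (adjusted p = 2.2e-11). The mean level of the identity genes was 11.01, and 10.87 to 11.06 under its alternatives. Under alternatives that change the ratios themselves, 111 of 113 values of the 21 ranked genes and 144 of 147 of the 28 other named genes kept their sign. Most of these values are the same probe on the same arrays processed otherwise. All signs that turned came from other probes of a gene, given below. With an array left out, 107 of 112 values of the other named genes kept their sign. The ranked genes were chosen for 1 sign on all arrays and at least a 1.5-fold change. For them neither renormalization nor leaving out an array is an independent check.

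With an array left out, signs turned for 4 named genes and for the medians of 12 of the 25 lists: the log2 ratio ranged from -0.070 to 0.46 for AMH, -0.16 to 0.68 for CYP11A1, -0.23 to 0.41 for CYP19A1 (each lowest without array 4), -0.41 to 0.67 for INHBA (-0.41 without array 2, -0.033 without array 1) and -0.12 to 0.058 for the LH surge list (highest without array 4). The median of cell cycle genes went from 0.017 to -0.27 without array 4, and that of extracellular matrix genes from -0.013 to 0.17 without array 3. Under other alternatives 7 of the 25 list medians turned, and all turned lists had a reported median of 0.059 or less in size. For single genes, the sign of the ratio turned with other probes of EPCAM (0.020), IL6 (0.014), KIF3A (-0.043), NR5A2 (-0.10) and PUSL1 (0.0021). The cause was not tested. Dim probes are limited by a median signal 1.11 to 1.20 times the background threshold.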

Other observations

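Other fixed lists did not pass, with adjusted p-values from 0.149 to 0.9503 (limma camera, preset correlation). Apoptosis and atresia genes had 16 of 19 members lower and a median of -0.11, and passed without array 1 (adjusted p = 0.0012). Cholesterol synthesis and uptake genes had 16 of 21 members higher and a median of 0.08, and passed without array 2 (adjusted p = 0.0017) and with median centring (adjusted p = 0.0431). Cell cycle genes had medians of -0.27, -0.46, -0.02 and 0.81 on arrays 1 to 4, and oocyte markers had -0.07, -0.19, 0.20 and -0.01. Markers of theca and stroma had 14 of 19 members lower and a median of -0.06, and passed without array 1 (adjusted p = 0.0349). Without array 1, insulin and IGF signalling passed upward (adjusted p = 0.0277), and without array 2 interferon response genes did (adjusted p = 0.0278). Without array 3, oxidative phosphorylation passed downward (adjusted p = 0.014) and extracellular matrix upward (adjusted p = 0.0093). Without array 4, cell cycle genes passed downward (adjusted p = 2.2e-11), and with median centring ribosomal proteins passed upward (adjusted p = 0.0375). All these calls used the preset correlation of 0.01. Over all arrays the estimated correlation of these lists ranged from 0.035 for theca and stroma markers to 0.74 for cell cycle genes. Members were lower for endothelial markers in 5 of 12, with a median of 0.03, and for erythrocyte markers in 4 of 6, with a median of -0.01.

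OVGP1, the oviductal glycoprotein, singled out after its values were seen, had log2 ratios of 4.48, -2.28, -3.62 and -0.50 on arrays 1 to 4. KRT18, a keratin of simple epithelia, had 1.74, -1.31, -2.82 and -0.58, and KRT8 had 1.25, -0.99, -2.37 and -2.07. All of these are members of the list of surface and oviduct epithelium markers.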
